A study of Homo sapiens with 21 samples.

How the data were processed

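Circular RNA was sequenced from 21 libraries of 3 human lung cell lines, in 7 groups of 3 libraries. Circular RNAs (circRNAs) are closed transcripts recognised by reads that cross a back-splice junction, where the end of an exon is joined to the start of an upstream one. Per the labels' protocols, total RNA was extracted with a column kit and a sequencing provider then purified the circular RNA and prepared the libraries. The deposited values are whole-number counts of reads per circRNA, without normalization. The submitters' processing notes name the genome build hg38 and the tools HISAT2, a read aligner, and DESeq2, a tool for differential counts, without versions or roles. The circRNA caller, its filters and the annotation are not given in the sources used here.

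The table held 124082 circRNAs and each of the 21 count columns was matched to a sample by its name. The circRNA identifiers run from 1 to 124082 without a gap. They were numbered by the first library, in column order, that held a read of the circRNA. They are therefore numbers of this table and not database accessions, and the table pairs them with no gene name, host gene or coordinate. For that reason no host gene was assigned, and no circRNA was matched to a known circRNA. The tests of host genes, of host gene lists and of a list of known circRNAs that were planned before the data were examined were not run. At most 2 identifiers that rose and 2 that fell are printed for a comparison. Whether the FASN plasmid raised its target was not analysed here, as the identifiers carry no gene name and the counts are of circular RNA alone.

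Library totals ran from 95808 to 203079 reads. Of the circRNAs in the table, 33302 (26.8%) had 1 read over all libraries, 59010 were read in 1 library alone and 2481 were read in all 21. Counts were analysed in R 4.3.3 with edgeR 4.0.16. filterByExpr with a minimum count of 5 and a minimum total of 15 kept 9175 circRNAs (7.39%), which held between 73.6% and 79.3% of the reads of a library. Scaling factors were computed by the trimmed mean of M values (TMM). One quasi-likelihood model with a mean for each of the 7 groups was fitted to all 21 libraries, with robust estimation of the spread, and each comparison was a contrast of that model. P-values were adjusted by the method of Benjamini and Hochberg within a comparison, and a circRNA was called at an adjusted p under 0.05. For 99.2% of the circRNAs tested, the spread was taken almost wholly from the trend fitted across circRNAs, so their p-values measure their differences against a spread shared with circRNAs of like abundance. The SE of a log2 change is its size divided by the square root of the F statistic of its test. It therefore rests on the spread used in that test and not on the compared libraries alone. CPM are the counts per M (mega) TMM-scaled reads in the circRNAs tested, as edgeR computes them, and log2 CPM used a prior count of 2.

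The test missed many simulated changes at these counts and with 3 libraries in a group. On simulated data with the means and totals of these libraries, 9175 circRNAs and 200 of them changed, drawn from those with a mean of at least 5 reads, the same code recovered 38% of 4-fold changes and 13% of 2-fold changes for gefitinib-resistant PC-9 cells. The figures were 40% and 5% for osimertinib-resistant NCI-H1975 cells, and 46% and 2% for FASN against pCMV6. Every simulated change that was called had the right direction in these comparisons. A circRNA with no read in a group was given a floor of 3 counts over that group, and its fold is then a lower bound. With 1 to 3 counts in a group, the ratio is given with its 95% exact conditional interval. These floors and intervals cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

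The labels do not say whether the 3 libraries of a group came from separate cultures. The spread behind the p-values, shared across circRNAs and the 7 groups, is therefore one between libraries and can be technical. No library was a copy of another: for circRNAs with at least 20 reads in a pair, the chi-square of counts per degree of freedom lay between 2.08 and 2.69 for pairs within groups, apart from 4.97 and 4.51 for the pairs that held osimertinib-resistant replicate 2.

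Comparisons made were each resistant line against the cells of the same line without a resistance code, FASN against pCMV6, pCMV6 against NCI-H1975, PC-9 and NCI-H1975 each against NL20, and NCI-H1975 against PC-9. A further contrast compared the changes in the resistant lines, and another compared the FASN with the osimertinib-resistance change. FASN against NCI-H1975 was added after the data were seen. The number of distinct circRNAs was compared after thinning every library to 95808 reads (mean of 100 draws), and the share of reads in the 10 most abundant circRNAs as deposited, both by exact two-sided permutation tests. With 3 libraries against 3 such a test cannot give a p under 0.1. The circRNAs printed are, by a rule set before the data were examined, those with the highest and lowest log2 fold change among the called circRNAs whose mean log2 CPM was at or above the median of those tested (6.03) and whose CPM did not overlap between the groups. The rule took 8 in each direction, of which the first 2 are printed. For the contrasts of changes the same rule was used without the condition on overlap. For FASN against NCI-H1975, with no call, only the circRNA with the smallest p is printed. The most abundant circRNA of the table was singled out after its values were seen.

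Alternatives were the scaling methods RLE and TMMwsp, no scaling factors, no filter on low counts, a minimum count of 10, the Wald test of DESeq2 1.42.0, a fit of the compared groups alone, the replicate number as a further term, and leaving out each library in turn. For comparisons that share libraries, unchanged groups were simulated 20 times with the fitted spread, and the covariance and correlations of their fold changes are given beside the observed ones. The overlap of calls in these simulations is not used, because unchanged groups give almost no calls.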

Results

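Back-splice reads of circular RNAs were counted in 21 libraries from NL20, PC-9 and NCI-H1975 cells. NL20 is an immortalized, non-tumorigenic bronchial epithelial line that served as the normal lung control. PC-9 and NCI-H1975 are EGFR-mutant lung cancer lines. PC-9 was sequenced as cells without a resistance code and as cells resistant to gefitinib, an EGFR tyrosine kinase inhibitor, which were kept in 1 µM of the drug. NCI-H1975 was sequenced without a resistance or plasmid code, after selection for resistance to osimertinib, a later EGFR inhibitor, kept at 1 µM, and after transfection with the plasmid pCMV6 or with FASN. FASN is fatty acid synthase, the enzyme that makes palmitate. Transfected cells received 50 µg/ml of the selection antibiotic G418. Each of the 7 groups had 3 libraries. The table identifies circRNAs by numbers of its own and does not pair them with gene names.

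The libraries held 178792 ± 22873 reads in NL20 (mean ± SD, n = 3), 143420 ± 44451 in PC-9, 115530 ± 5957 in gefitinib-resistant PC-9 and 152489 ± 16247 in NCI-H1975. They held 130093 ± 17314 in osimertinib-resistant NCI-H1975, 101381 ± 7927 in pCMV6 and 120007 ± 23547 in FASN cells. Cell line was the largest source of difference between libraries. The Spearman correlation of log2 CPM across circRNAs had a median of 0.671 for pairs of libraries within a group, 0.598 between groups of a line and 0.383 between lines. The first principal component, with 27.3% of the variance, placed PC-9 and NCI-H1975 apart, and the second, with 13.4%, set NL20 apart from both cancer lines. Osimertinib-resistant replicate 2 stood away from the other libraries on the third (6.9%), at -76.4 against -27.7 and -33.5 for the other libraries of its group.

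The most abundant circRNA of the table, hsa_circ_11052, took 94157 reads. It was read in every library, with its highest shares in the NCI-H1975 groups. It held 5.99% ± 0.22 of the reads in NCI-H1975 (SD, n = 3), 6.05% ± 0.14 in FASN cells, 2.98% ± 0.042 in pCMV6 cells and 8.67% ± 2.36 in osimertinib-resistant cells, against 0.324% ± 0.020 in NL20 and 0.146% ± 0.021 in PC-9. At equal depth, NL20 showed 22624 ± 493 distinct circRNAs, NCI-H1975 21145 ± 804, FASN cells 20787 ± 663, gefitinib-resistant PC-9 20639 ± 512 and PC-9 20625 ± 934. The pCMV6 cells showed 18592 ± 218, fewer in every library than any FASN or NCI-H1975 library, but this turned round when at least 2 reads were required, with 336 more on average than NCI-H1975 and a FASN minus pCMV6 difference of -303. PC-9 minus NL20 turned round likewise, to 237, and NCI-H1975 minus NL20 shrank to -91.9. Osimertinib-resistant cells showed 18197 ± 3154, with 14701 in replicate 2 alone, and their difference from NCI-H1975 shrank from -2948 to -1200 without that library and to -417 when at least 2 reads were required. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows, for PC-9 against NL20, NCI-H1975 against NL20, FASN against pCMV6 and pCMV6 against NCI-H1975, with 0.127 after adjustment over 14 tests. For the osimertinib-resistant cells against NCI-H1975 the permutation p was 0.2, for NCI-H1975 against PC-9 0.6 and for gefitinib-resistant against other PC-9 cells 1.

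The 10 most abundant circRNAs of a library held 12.6% ± 2.43 of the reads in osimertinib-resistant cells (SD, n = 3), 10.1% ± 0.213 in NCI-H1975, 10.1% ± 0.222 in FASN cells and 7.23% ± 0.164 in pCMV6 cells. They held 3.81% ± 0.0178 in gefitinib-resistant PC-9, 3.64% ± 0.0405 in PC-9 and 3.74% ± 0.0545 in NL20. In each of the 7 planned comparisons the libraries of a group lay all above or all below those of the other, with an exact permutation p of 0.1 and 0.127 after adjustment over the 14 tests.

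**Figure D1:**
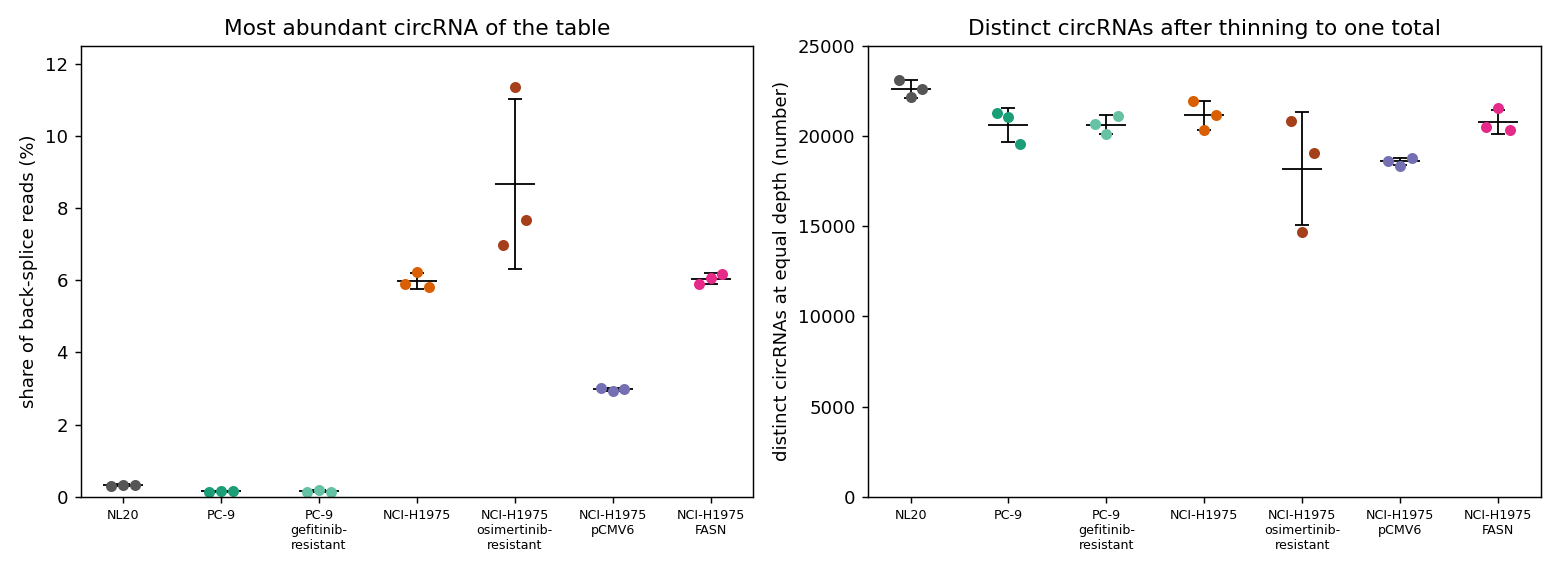
Share of back-splice reads taken by the most abundant circRNA (left, percent) and distinct circRNAs after thinning to one total (right, number) in each library, with points for libraries and bars for the mean ± SD of 3 libraries. The share lay between 5.82% and 6.23% in NCI-H1975 and between 2.94% and 3.02% in pCMV6 cells, and osimertinib-resistant replicate 2 reached 11.4%.

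The gefitinib-resistant PC-9 cells were compared with PC-9 cells to ask which circRNAs go with resistance in that line. hsa_circ_17994 had 14 reads in the resistant libraries and none in the others, at least 5.6-fold higher. hsa_circ_17356 rose from 3.97 ± 6.87 to 94.7 ± 15.7 CPM (SD, n = 3), with 25 reads against 1 and a ratio of 30.0 (95% interval 4.91 to 1232). Lower in the resistant cells were hsa_circ_28162, with no read against 24 and at least 6.66-fold lower, and hsa_circ_8024, with no read against 18 and at least 5-fold lower. All 4 were also read in NCI-H1975 cells, hsa_circ_17994 at 114.8 ± 38.4 CPM and hsa_circ_8024 at 147.5 ± 35.0 CPM. edgeR's quasi-likelihood test called 124 circRNAs, 67 higher and 57 lower, and 1018 had an unadjusted p under 0.05. The adjusted p of the 4 was 0.023, 0.0103, 0.0161 and 0.0146 in that test. Among the 100 most abundant circRNAs tested, 15 were higher and 8 lower, with a median size of 0.90 on the log2 scale against 1.55 for all calls. Leaving out any of the 6 libraries lowered the count to between 48 and 72, and the calls of hsa_circ_17994, hsa_circ_28162 and hsa_circ_8024 then held in 1 of 6 fits each and that of hsa_circ_17356 in 3. The count was 16 without the filter on low counts, 211 with DESeq2 and 233 in a fit of these 6 libraries alone.

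Osimertinib-resistant NCI-H1975 cells had circRNAs that NCI-H1975 cells lacked and lacked others that NCI-H1975 cells had. The smallest p was that of hsa_circ_85923, which stood at 909.6 ± 16.6 CPM (SD, n = 3) with 265 reads and had none in NCI-H1975, at least 103-fold higher (edgeR quasi-likelihood test, adjusted p = 1.02e-36). The circRNA numbered before it, hsa_circ_85922, had 53 reads against none, at least 20.6-fold higher (edgeR adjusted p = 5.31e-06). Neither had a read in pCMV6, FASN or NL20 libraries. Both were circRNAs of PC-9, where hsa_circ_85923 stood at 556.5 ± 134.8 CPM and at 864.2 ± 140.4 in the gefitinib-resistant cells. Other circRNAs were lost. hsa_circ_1242 fell from 192.4 ± 78.9 CPM and 67 reads to none, at least 19.1-fold lower, and hsa_circ_18450 from 113.5 ± 35.1 CPM and 38 reads to none, at least 10.8-fold lower (edgeR adjusted p = 4.44e-06 and 4.08e-05). Both were kept in pCMV6 cells, at 174.9 ± 62.7 and 130.5 ± 57.3 CPM, and in FASN cells, at 143.8 ± 79.1 and 148.1 ± 42.5 CPM. hsa_circ_1242 was read in no PC-9 or NL20 library.

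**Figure D2:**
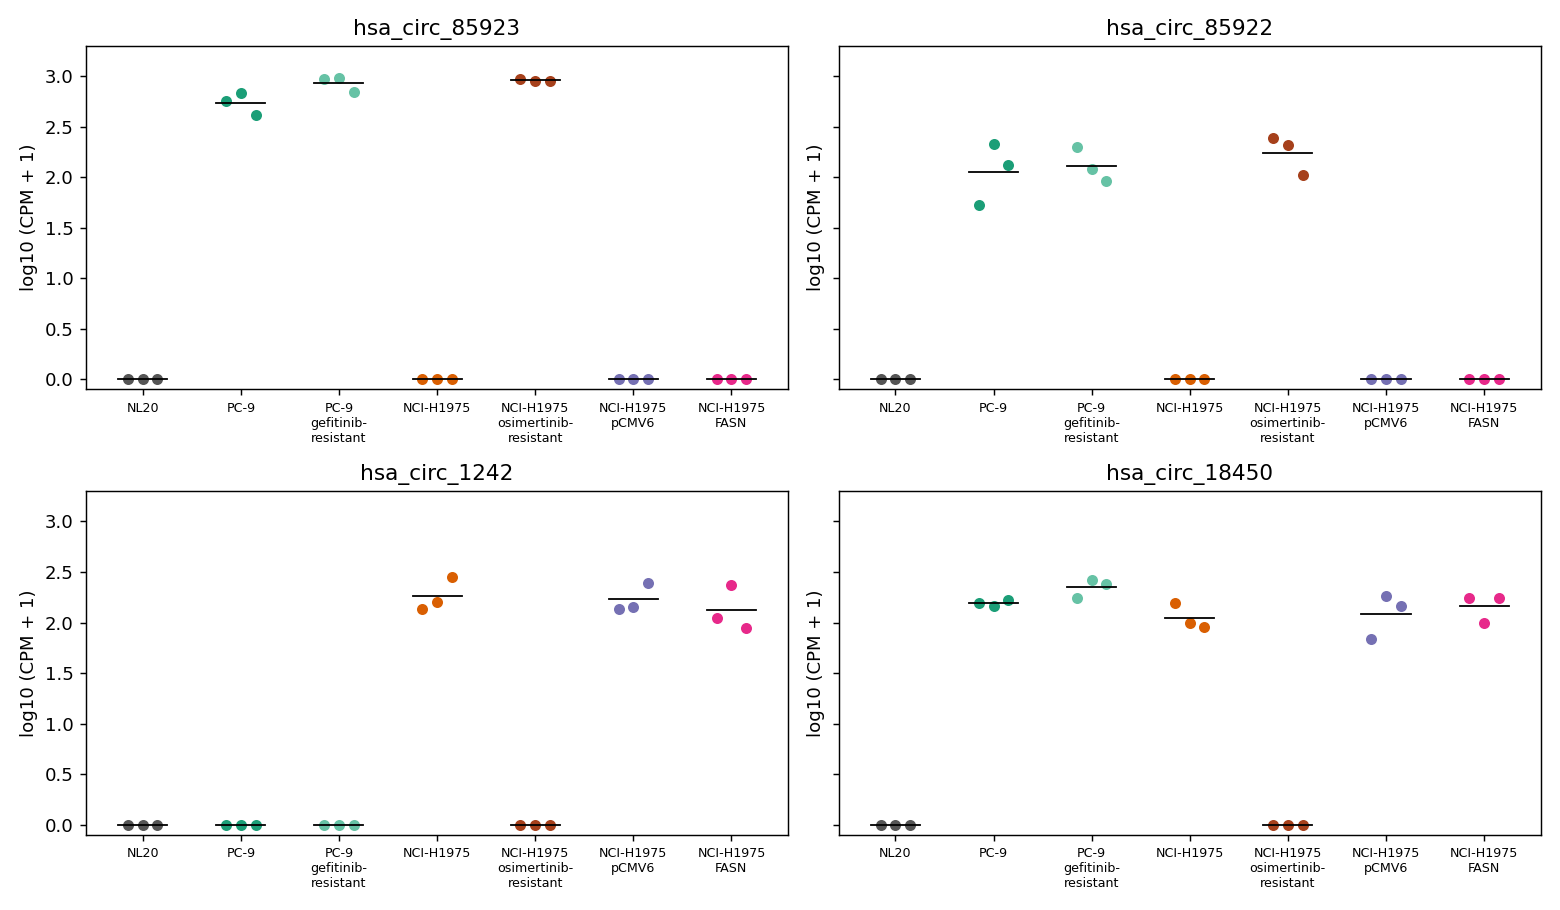
Level of 4 circRNAs in each of the 21 libraries, as log10 of CPM plus 1, with points for libraries and lines for the group means of the plotted values. hsa_circ_85923 and hsa_circ_85922 were read in the PC-9 groups and in the osimertinib-resistant NCI-H1975 libraries alone, and hsa_circ_1242 and hsa_circ_18450 had no read in the osimertinib-resistant libraries.

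Over all circRNAs tested, edgeR's quasi-likelihood test called 231 in the osimertinib-resistant cells, 125 higher and 106 lower, with 1276 at an unadjusted p under 0.05. Of these, 14 higher circRNAs had no read in NCI-H1975 and 16 lower ones had none in the resistant cells. The most abundant circRNA rose 1.43-fold (log2 0.52 ± 0.09 SE, edgeR adjusted p = 3.06e-06). This rise rested in part on osimertinib-resistant replicate 2: without it the log2 change was 0.31 and the edgeR adjusted p 0.0687. The adjusted p was 0.46 without the filter on low counts and 0.119 in a fit of the 6 libraries alone. Without that library, which had the fewest distinct circRNAs, 159 circRNAs were called, and 138 of them were among the 231. Leaving out a NCI-H1975 library gave 115, 125 and 115 calls for replicates 1, 2 and 3, and 53 were called without the filter.

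Few circRNAs were called in the same direction in both resistant lines. For circRNAs with a mean of at least 5 reads, the tests recovered 38% and 40% of simulated 4-fold changes and 13% and 5% of 2-fold changes. The median circRNA tested had 4.67 reads per library, and changes below that mean of 5 were not simulated. Shared changes can therefore be missed. Of the calls, 3 were higher in both, where independent lists would share 0.913, and 5 were lower in both, where they would share 0.659. The one-sided exact hypergeometric p was 0.063 for the higher and 0.000486 for the lower circRNAs, or 0.063 and 0.000973 after adjustment over both tests, which treat circRNAs as independent. A further 5 were called in opposite directions. At an unadjusted p under 0.05, 47 were higher in both against 33.2 for independent lists, 59 were lower in both against 37.5, and 74 went opposite ways. The Spearman correlation of the fold changes across circRNAs, which are not independent replicates, was 0.033. The difference between the changes was tested as an interaction. edgeR's quasi-likelihood test called 162 circRNAs for it, of which 76 had a higher log2 change in PC-9 and 86 a higher one in NCI-H1975. They included hsa_circ_18450, which was lost in osimertinib-resistant cells and stood at 155.8 ± 10.4 CPM in PC-9 and 225.5 ± 45.0 CPM in gefitinib-resistant PC-9 (SD, n = 3). They also included hsa_circ_85923. With 1 of the 12 libraries left out, between 79 and 141 were called, and DESeq2 called 248 and the test without the filter 21.

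FASN-transfected cells were compared with pCMV6-transfected cells, the plasmid control, to ask which circRNAs go with FASN. hsa_circ_38806 had 48 reads in FASN cells and none in pCMV6 cells, at least 14.2-fold higher, and hsa_circ_39396 had 44 against none, at least 13.0-fold higher (edgeR quasi-likelihood test, adjusted p = 0.000125 and 1.69e-06). Both were also read in NCI-H1975 cells without a plasmid code, with 24 and 29 reads, so what sets these groups apart is their absence from the pCMV6 libraries. hsa_circ_11450 stood at 4.11 ± 7.12 CPM against 283.2 ± 44.5 (SD, n = 3), with 1 read against 69, and was lower by a ratio of 77.6 (95% interval 13.5 to 3110). hsa_circ_19078 had no read against 17, at least 6.38-fold lower (edgeR adjusted p = 0.00988), and its call held in 2 of the 6 fits that left out a library. NCI-H1975 cells without a plasmid code had 31 reads of hsa_circ_11450 and 14 of hsa_circ_19078, so FASN cells held the fewest of both. Neither was called between FASN and NCI-H1975 cells. In FASN cells the most abundant circRNA was 2.13-fold higher (log2 1.09 ± 0.09 SE, edgeR adjusted p = 2.46e-29). Its adjusted p was 4.04e-08 in the Wald test of DESeq2 and 2.24e-07 in edgeR's test with a minimum count of 10. In all, 29 circRNAs were called, 18 higher and 11 lower, and 729 had an unadjusted p under 0.05. Without scaling factors 14 were higher and 16 lower, and with the most abundant circRNA removed before scaling 22 were higher and 7 lower. Leaving out a library gave between 14 and 20 calls, fewer than the full set by over 1.5 times for each library except pCMV6 replicate 2, and 8 were called without the filter.

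The pCMV6 cells also differed from NCI-H1975 cells that carried no plasmid code. hsa_circ_39087 fell from 129.3 ± 50.4 CPM (SD, n = 3) and 44 reads to none, at least 10.5-fold lower, and hsa_circ_51016 from 116.4 ± 40.8 CPM and 39 reads to none, at least 9.28-fold lower (edgeR quasi-likelihood test, adjusted p = 0.00462 and 0.00423). With a library left out, these calls held in 4 and 5 of 6 fits. hsa_circ_18612 was higher, with 25 reads against 1 and a ratio of 35.0 (95% interval 5.73 to 1438, edgeR adjusted p = 0.0282), but its call held in 0 of the 6 fits that left out a library. hsa_circ_13854 was also higher, at 413.6 ± 51.5 against 133.0 ± 36.7 CPM, a ratio of 3.08, and stood at 145.6 ± 19.6 CPM in FASN cells (edgeR adjusted p = 0.00834), and its call held in 2 of those fits. In pCMV6 cells the most abundant circRNA was lower (log2 -1.11 ± 0.09 SE, edgeR adjusted p = 4.63e-30). Its adjusted p was 7.23e-08 in the Wald test of DESeq2 and 3.14e-07 in edgeR's test with a minimum count of 10. In all, 33 circRNAs were called, 11 higher and 22 lower, with 722 at an unadjusted p under 0.05. With the most abundant circRNA removed before scaling, 7 were higher and 30 lower. Leaving out any of the 6 libraries gave between 9 and 21 calls, DESeq2 called 53, and 12 were called without the filter. Calls against NCI-H1975 overlapped with those of osimertinib-resistant cells, with 6 higher in both, 5 lower in both and 3 opposite. Independent lists would share 0.15 higher and 0.25 lower. The covariance of the log2 fold changes was 0.60, against 0.48 in simulated unchanged groups that share the NCI-H1975 libraries. The Pearson and Spearman correlations were 0.33 and 0.32, beside 0.45 and 0.43 simulated. Part of the overlap can come from those shared libraries.

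FASN cells and NCI-H1975 cells, a comparison added after the data were seen, gave no call with edgeR's quasi-likelihood test and none with DESeq2, and 336 circRNAs had an unadjusted p under 0.05. Without NCI-H1975 replicate 2, edgeR called 1. The smallest adjusted p was 0.072, for hsa_circ_11450, which had 31 reads in NCI-H1975 and 1 in FASN cells. For the most abundant circRNA there was a log2 difference of -0.01 ± 0.09 SE. Calls of FASN against pCMV6 and of pCMV6 against NCI-H1975 overlapped in opposite directions. Of the circRNAs higher in FASN than in pCMV6 cells, 15 were also lower in pCMV6 than in NCI-H1975 cells, where independent lists would share 0.043, and 4 went the other way in both, against 0.013. The covariance of the log2 fold changes was -1.14, against -0.62 in simulated unchanged groups that share the pCMV6 libraries. The Pearson correlation was -0.66 and the Spearman correlation -0.61, beside -0.54 and -0.49 simulated. Part of the overlap can come from the shared pCMV6 libraries, of which there are too few to split.

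The FASN change, measured against pCMV6 cells, was also set against the osimertinib-resistance change in the same line. FASN against NCI-H1975 gave no call, but the comparisons that were simulated missed many changes at these counts. Besides any change with FASN, the FASN change here holds whatever set the pCMV6 libraries apart. The difference between the FASN and the osimertinib-resistance change was called for 191 circRNAs by edgeR's quasi-likelihood test. Of these, 109 had a higher log2 change for FASN and 82 a lower one. hsa_circ_37009 and hsa_circ_39087 had no read in pCMV6 cells and 31 and 23 in FASN cells (edgeR adjusted p of the difference between changes = 3.53e-05 and 0.00335). They had 20 and 44 reads in NCI-H1975 and 8 and 13 in osimertinib-resistant cells, and neither was called between those groups. hsa_circ_15042 and hsa_circ_4220 went the other way, with no read in FASN cells and 5 and 10 in pCMV6 cells, against 4 and 17 in osimertinib-resistant and 0 and 5 in NCI-H1975 cells (edgeR adjusted p = 0.0429 and 0.0119). With a library left out, their calls held in 1 and 7 of 12 fits. Without FASN replicate 1 the count was 122 and without NCI-H1975 replicate 1 it was 121. DESeq2 called 294, and 38 were called without the filter.

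The cancer lines were compared with NL20 as the normal lung control. In PC-9, hsa_circ_104535 stood at 3624 ± 520 CPM (SD, n = 3) with 1173 reads and hsa_circ_2642 at 2632 ± 425 CPM with 814 reads, and NL20 had no read of either, so that they were at least 483-fold and at least 335-fold higher (edgeR quasi-likelihood test, adjusted p = 3.36e-127 and 2.73e-124). hsa_circ_20528, with 482 reads in NL20, and hsa_circ_18923, with 312, had none in PC-9 and were at least 129.9-fold and at least 84.1-fold lower (edgeR adjusted p = 2.43e-34 and 1.11e-36). The test called 1539 circRNAs, 828 higher and 711 lower in PC-9, of which 295 of the higher had no read in NL20 and 155 of the lower none in PC-9. Without the filter on low counts 679 were called.

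In NCI-H1975, hsa_circ_6671 stood at 5173 ± 291 CPM (SD, n = 3) with 1766 reads and had none in NL20, at least 680-fold higher, and hsa_circ_2642 stood at 941.9 ± 76.2 CPM, at least 123.7-fold higher (edgeR quasi-likelihood test, adjusted p = 9.24e-192 and 1.83e-77). hsa_circ_64888, with 1642 reads in NL20, and hsa_circ_60454, with 997, had none in NCI-H1975 and were at least 474-fold and at least 288-fold lower (edgeR adjusted p = 4.84e-99 and 4.09e-88). Relative to NL20, the most abundant circRNA was 18.2-fold higher. In all, 1500 circRNAs were called, 783 higher and 717 lower. Without NL20 replicate 1 the count was 951, without NL20 replicate 2 it was 952, without NCI-H1975 replicate 2 it was 985, and without the filter 565.

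Calls against NL20 overlapped between the cancer lines. The circRNAs higher in both numbered 248, against 70.7 for independent lists, and those lower in both 239, against 55.6, while 66 went opposite ways. hsa_circ_2642 was among those higher in both. The covariance of the log2 fold changes was 1.77, against 0.44 in simulated unchanged groups that share the NL20 libraries. The Pearson correlation across circRNAs was 0.43 and the Spearman correlation 0.38, beside 0.48 and 0.45 simulated. Changes particular to a line, which the simulated groups lack, lower a correlation, so these values do not settle how much of the overlap is shared. Part of the excess can come from the shared NL20 libraries, of which there are too few to split.

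Compared with each other, the cancer lines differed in 1817 circRNAs by edgeR's quasi-likelihood test, 909 higher in NCI-H1975 and 908 higher in PC-9. hsa_circ_6671, with no read in PC-9, was at least 550-fold higher in NCI-H1975, and hsa_circ_10548, with 446 reads against none, at least 138.9-fold higher. hsa_circ_104535, with no read in NCI-H1975, was at least 418.4-fold lower there, and hsa_circ_48935, with 412 reads in PC-9, at least 146.9-fold lower. Of the 100 most abundant circRNAs tested, 70 were called, 38 higher and 32 lower in NCI-H1975. Without the filter 772 circRNAs were called.

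**Figure D3:**
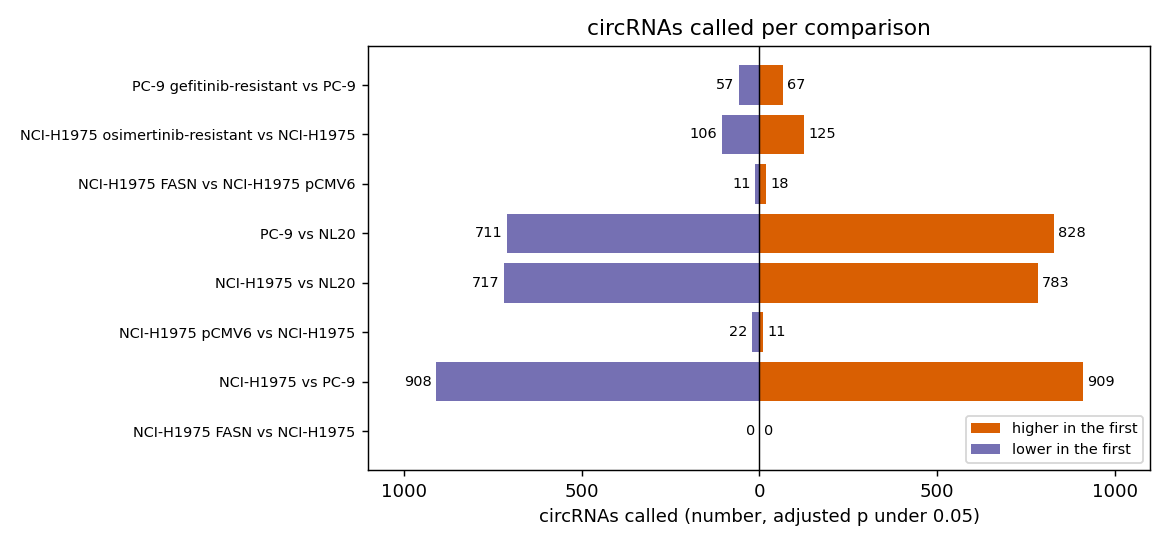
Number of circRNAs called at an adjusted p under 0.05 in 8 comparisons, as bars to the right for circRNAs higher and to the left for circRNAs lower in the first group named. Comparisons between cell lines gave 1500 to 1817 calls, and those within a line 0 to 231.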

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

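Of the tests in this part, those for RNA of NL20 or PC-9 in the osimertinib-resistant libraries were chosen only after the result was seen.

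The change with gefitinib resistance in PC-9 and the change with osimertinib resistance in NCI-H1975 differed by a test of the difference itself, which called 162 circRNAs. Only 2 of 100 splits of the libraries within each line, the real one included, gave as many. The other split, with 199 circRNAs, exchanged the whole resistant and other groups of one line, which adds the changes in place of subtracting them, and the highest of the remaining splits gave 63. Splits that mix the groups undo the change within each line. The share therefore bears on whether the groups differ at all and cannot decide whether the changes differ. The difference of fitted log2 changes, PC-9 minus NCI-H1975, was 7.06 for hsa_circ_18450, 6.50 for hsa_circ_9962, -8.90 for hsa_circ_85923 and -7.20 for hsa_circ_85922. These fitted values depend on the default prior count of edgeR's fit, which is not the 2 used for log2 CPM. Each of the 4 circRNAs had no read in one of the NCI-H1975 groups. hsa_circ_9962 had 19 reads in NCI-H1975, none in osimertinib-resistant cells and 27 and 46 in PC-9 and gefitinib-resistant PC-9 cells, and its call was lost without the filter on low counts.

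Some circRNAs were read in all 3 osimertinib-resistant libraries and in no other NCI-H1975 library. There were 44, of which 11 had at least 10 reads, and 9 of the 11 were read in PC-9 and 7 in NL20. Having such circRNAs is not peculiar to resistance: NCI-H1975 had 83 of its own within the line, 10 of them with at least 10 reads and at most 17, while the highest in the resistant cells was hsa_circ_85923 with 265. PC-9 RNA in the resistant libraries is argued against by the other 50 circRNAs of PC-9 that NCI-H1975 and NL20 lacked. Their median level in the resistant libraries, as a share of all reads without scaling factors, was 0% of that in PC-9. By the same measure hsa_circ_85923 stood at 165% of its PC-9 level. Beyond hsa_circ_85922, the remaining 49 had 11 reads in the resistant libraries against 5572 in PC-9. NL20 RNA is argued against in the same way, as 27 circRNAs of NL20 stood at a pooled 0.960% of their NL20 level. A change in the resistant cells stays a hypothesis, and whether it came with resistance or with a subclone carried through selection was not tested.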

How the results depend on the processing

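The comparison of FASN with NCI-H1975, the fits at one total, those without the most abundant circRNA and the overlap without osimertinib-resistant replicate 2 were chosen after the data were seen. Scaling by RLE, TMMwsp or totals alone and a minimum count of 10 kept every count of called circRNAs within 1.5 times. Without the filter on low counts, which spreads the adjustment over 124082 circRNAs and changes the fitted spread, calls fell to 16 for gefitinib resistance, 53 for osimertinib resistance, 8 for FASN against pCMV6, 12 for pCMV6 against NCI-H1975, 679 and 565 for PC-9 and NCI-H1975 against NL20, 772 between the cancer lines, and 21 and 38 for the interactions of gefitinib and of FASN with osimertinib resistance. DESeq2 called 211, 53, 248 and 294 for gefitinib resistance, pCMV6 against NCI-H1975 and these interactions. A fit of the compared libraries alone called 233 for gefitinib resistance. The cause of these moves was not tested.

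With 1 library left out, which lowers the number of samples, calls ranged from 48 to 72 for gefitinib resistance, 115 to 176 for osimertinib resistance, 14 to 20 for FASN against pCMV6, 9 to 21 for pCMV6 against NCI-H1975, 1045 to 1173 and 951 to 1064 for PC-9 and NCI-H1975 against NL20, 1214 to 1382 between the cancer lines, 79 to 141 and 121 to 165 for the interactions, and 0 to 1 for FASN against NCI-H1975. The 36 named results kept their direction under every alternative that gave a value. Their calls held in all 36 under each scaling, in 33 of 33 with DESeq2, 34 of 34 with a minimum count of 10, 29 of 30 in fits of the compared libraries, 26 of 36 without the filter and 213 of 264 with a library left out.

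At one total of 95808 reads, FASN against pCMV6 gave 23 calls and pCMV6 against NCI-H1975 27. The overlap of the resistance calls was 8, was 7 without osimertinib-resistant replicate 2, and 106 at an unadjusted p under 0.05, which admits more circRNAs.

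The replicate numbers did not pair the libraries: deviations from group means correlated at -0.00449 on average for the same number, and 6 of the 21 libraries correlated best with their own number. A replicate block gave 111 calls for gefitinib resistance, 208 for osimertinib resistance, 24 for FASN against pCMV6 and 32 for pCMV6 against NCI-H1975, and 34 of 36 named calls held under it.

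Differences in distinct circRNAs at equal depth turned round when at least 2 reads were required, to 237 for PC-9 minus NL20, -303 for FASN minus pCMV6, 336 for pCMV6 minus NCI-H1975, -329 for NCI-H1975 minus PC-9 and -189 for gefitinib-resistant minus other PC-9. NCI-H1975 minus NL20 shrank from -1478 to -91.9 and osimertinib-resistant minus NCI-H1975 from -2948 to -417 (-4264 to -1200 with a library left out). For gefitinib resistance the difference was -1495 without thinning and ran from -522 to 334 with a library left out, and NCI-H1975 minus PC-9 ran from -15.8 to 923.5. The cause was not tested.

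With 10 splits of 6 libraries, a comparison cannot give a share under 0.05. In each of the 7 planned comparisons 1 split, the real one, reached its count. The highest other split called 0 against the real 124 for gefitinib resistance, 8 against 231 for osimertinib resistance, 0 against 29 for FASN and pCMV6, 1 against 33 for pCMV6 and NCI-H1975, 1 against 1539 and 0 against 1500 for PC-9 and NCI-H1975 against NL20, and 0 against 1817 between the cancer lines. All 10 called 0 for FASN and NCI-H1975. For the interaction of FASN with osimertinib resistance, 1 of 100 splits, the real one, gave 191, and the highest other gave 81. Mixing the groups also undoes the changes themselves, so these splits cannot decide whether the changes differ. Tests of host genes, host gene lists and known circRNAs were not run, as the identifiers carry no gene or coordinate.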

Other observations

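Of the tests in this part, those for NL20 or PC-9 RNA in the pCMV6 libraries, for the depth of osimertinib-resistant replicate 2 and for neighbouring identifiers were chosen only after the result was seen.

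Many circRNAs were common to the lines. Of those read in all 3 libraries of a group, 4347 were read in every library of NL20, PC-9 and NCI-H1975, and 2481 in all 21 libraries. The next counts used only the libraries of the lines without a resistance or plasmid code. Among these, circRNAs read in all 3 libraries of 1 line and in no library of the others numbered 556 in NL20, 453 in PC-9 and 348 in NCI-H1975. Resistant and transfected libraries can hold reads of them. A stricter set, with at least 30 reads, held 19 circRNAs of NCI-H1975. The median level of its members, against that in NCI-H1975, was 103% in FASN cells, 81.2% in pCMV6 cells and 58.3% in osimertinib-resistant cells. Levels here are shares of all reads of a library, without scaling factors. The set was chosen by its reads in the same NCI-H1975 libraries, which can lower the levels of the other groups beside them. The pooled levels of 108%, 56.1% and 53.9% are dominated by hsa_circ_6671, with 1766 of the 2795 reads of the set in NCI-H1975.

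The pCMV6 libraries differed from FASN and from NCI-H1975 libraries, which gave no call against each other. Lower depth is argued against: with all 9 libraries thinned to one total, FASN against pCMV6 still had 23 calls (20 to 25 over 5 draws) and FASN against NCI-H1975 had 0. The share of the most abundant circRNA is argued against as the whole cause, since 24 of the other 28 calls were kept with it removed. Cells of NL20 or PC-9 in the pCMV6 libraries are argued against by circRNAs of those lines that NCI-H1975 lacked, which reached at most 1.01% of their own-line level. An effect of the empty plasmid, a difference between the cultures and a library batch stay open and were not tested. The FASN comparison then holds, besides any change with FASN, whatever set the pCMV6 libraries apart.

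Osimertinib-resistant replicate 2 had 14701 distinct circRNAs at equal depth against 20829 and 19061 in the other libraries of its group, and 11.4% of its reads in the most abundant circRNA against 6.98% and 7.66%. Depth is argued against for circRNAs with at least 1 read, as the gap to the lower of the other libraries at one total was -22.9%. With at least 2 reads required, the counts at one total were 10719 against 11893 and 11849, a gap under 10%, so the shortfall lies mainly in circRNAs read once. The share of the most abundant circRNA is also argued against, for circRNAs with at least 1 read, as the gap was -22.5% with that circRNA removed. Loss of rare molecules before amplification and a difference between cultures stay open, and no biological explanation was tested. Its total of 110456 reads was also the total of pCMV6 replicate 1. Those libraries were not copies, with 15244 and 19494 distinct circRNAs, and why the totals are equal was not tested.

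circRNAs with neighbouring identifiers changed together. Because identifiers follow the first library that holds a circRNA, this was tested within the 7285 tested circRNAs first numbered from pCMV6 replicate 1. Between lines, the Spearman correlation of log2 fold changes of adjacent circRNAs was at least 0.29, against at most 0.039 in 1000 shuffled orders, and fell to between 0.035 and 0.065 for those 50 places apart. It was 0.111 for gefitinib and 0.158 for osimertinib resistance. FASN against pCMV6 and pCMV6 against NCI-H1975 gave 0.0647 and 0.0649, weak but above their highest shuffled values of 0.0376 and 0.0315. FASN against NCI-H1975 gave 0.018, within the shuffled range. A candidate explanation is that identifiers follow genome order within a library, so that neighbours such as hsa_circ_85922 and hsa_circ_85923 may share a locus. The called circRNAs may then stand for fewer independent changes than their number. No coordinate was used to check this.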
